A study of Mus musculus with 3 samples.

How the data were processed

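CD45-positive cells were sorted from CT26 tumours of mice given vehicle, MCB-294 or MCB-36, and each of the 3 groups is 1 droplet library of 3' RNA ends with molecular identifiers (10x Genomics chemistry). The labels give male mice and the strain C57BL/6, whereas the CT26 line is of BALB/c origin and would be mismatched in a C57BL/6 host, and nothing in the files settles the strain. They call the sorted cells CD45-positive in one place and CD45-positive T cells in another. The number of mice per library is not given. The deposited matrices hold raw UMI counts per gene and barcode, made with Cell Ranger 5.0.1 per the file headers, and the submitters' processing notes also name STAR, Seurat 4.1.1 and the genome build mm10. The files had been limited to cell barcodes by the authors, with a lowest total of 500 UMIs, and hold 32285 genes. How the barcodes were chosen is not stated, and empty droplets are not in the files, so free RNA could be measured only through genes of other cell types.

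From the counts, barcodes with at least 200 genes and at most 10% mitochondrial UMIs were kept. In vehicle, MCB-294 and MCB-36, 696, 677 and 725 barcodes exceeded the mitochondrial limit and 1, 2 and 24 had too few genes, which left 8631, 7693 and 10314. Doublets were removed within each library by a score from 2 simulated doublets per barcode, taking the highest scores at a rate of 0.8% per 1000 barcodes, which removed 596, 473 and 851. The 8035, 7220 and 9463 cells kept had medians of 12986, 14157 and 10579 UMIs and 3130, 3280 and 2713 genes. All 24718 cells were clustered together without integration on log counts per 10000, with 2000 variable genes (no mitochondrial, ribosomal, sex-linked, immunoglobulin or T cell receptor genes), 30 principal components, 15 neighbours and Leiden clustering at resolution 1, and T and NK clusters were clustered again, giving 34 clusters.

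Clusters were named from 20 fixed marker sets by the mean marker level relative to the highest cluster. A name needed a score of at least 0.45, a margin of 0.05 over the next class, 3 markers detected in 10% of cells, and no other class leading among the 10 leading genes, and other clusters stayed unnamed but within the total. For gene levels, raw UMIs were summed per library and class and given as CPM (counts per 1000000). The 7 classes with at least 100 cells in each library were compared, on genes with at least 50 UMIs over the 2 libraries of a comparison. Shares carry exact Clopper-Pearson intervals, CPM exact Poisson intervals and ratios of CPM exact conditional binomial intervals. Ratios of shares, and ratios between numbers of barcodes with markers of 2 cell types, carry approximate log-scale intervals. All are at 95% and for counting error only. With 1 library per group and cells not being replicates, no p-value and no number of genes changed by a compound was computed. Genes that differ between libraries were left out of 1 added clustering. They had at least 100 CPM in 1 library of a compared class and a 1.5-fold difference between libraries there. That cut takes no account of error, so their number is not a number of changed genes.

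Gene lists, markers, comparisons, filters, the rule for named genes and the main alternatives were fixed before the data were examined. The 21 lists were RAS genes, MAPK output, type I interferon, interferon-gamma, MHC class I, MHC class II, cytotoxic effector, exhaustion, naive and memory T, T cell activation, Treg activation, inflammatory cytokine, alternative and suppressive macrophage, complement with lipid and phagocytosis, monocyte and dendritic chemokine, neutrophil granule and maturation, proliferation, hypoxia and glycolysis, heat shock and dissociation, unfolded protein and integrated stress, and p53 and apoptosis. A list with at least 5 measured members is given as its median log2 ratio beside the range of 95% of 10000 random lists of equal size matched on expression in 20 bins. A list member is called higher or lower where its counting interval excludes a ratio of 1. Which lists are described in which class was chosen after a first look at every pair of list and class.

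Named genes were, for each comparison with vehicle and each of the 4 named classes with the most cells, the 4 with the highest and the 4 with the lowest log2 ratio among genes with at least 100 CPM in 1 library and a 1.5-fold difference. Between the compounds 2 of each were taken. As a guard against free RNA, a gene had to reach 0.1 of its highest level in any named class, and mitochondrial, ribosomal, haemoglobin, immunoglobulin, T cell receptor, sex-linked and unnamed gene models were left out. Up to 4 members of each described list with the largest ratios were added. The strain check planned on H2-Ea gave no value, because neither it nor its pseudogene name is among the genes of the files, and Mx1 and Mx2 of the interferon list are absent too.

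On data simulated from the MCB-294 and vehicle counts, where 200 genes were given known differences, the intervals and directions were tested before use. The counts were Poisson draws, the error that the intervals assume, without differences between cells or mice. The simulation therefore checks the computation and the effect of depth, and cannot say how well the intervals cover differences between libraries. The alternatives chosen beforehand were 9 for shares (filters, doublets, resolution, separate clustering, classes per cell, total, thinned UMIs) and 7 for genes and lists (TMM, median of ratios, UMI minimum, mean over cells, doublets, mitochondrial limit, thinned UMIs). Another 3 were added after seeing the data. The work used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16.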

Results

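White blood cells from CT26 tumours, a transplanted mouse colon carcinoma line, were profiled by droplet-based single-cell RNA sequencing to learn how the compounds MCB-294 and MCB-36 act on the tumour microenvironment. The study's title describes the compounds as a pan-KRAS inhibitor and a degrader derived from it. Mice given vehicle gave 1 library, mice given MCB-294 at 30 mg/kg gave 1 and mice given MCB-36 at 60 mg/kg gave 1, all after 2 days. Each group was therefore 1 library, the number of mice behind it is not stated, and no difference below has a replicate check. The vehicle library held 138327353 UMIs (unique molecular identifiers, each 1 captured RNA molecule) over 9327 barcodes, the MCB-294 library 129945937 UMIs over 8370 barcodes and the MCB-36 library 139434007 UMIs over 11039 barcodes. After filtering and removal of predicted doublets, 8035 vehicle, 7220 MCB-294 and 9463 MCB-36 cells were kept. Levels are counts per 1000000 UMIs (CPM) of the summed cells of a class, and ratios are log2 ratios of CPM. Parentheses hold 95% intervals, exact for counts, shares and ratios of CPM and approximate for ratios of shares, which cover counting error only.

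The kept cells fell into 14 named classes, each called "like" its type because the names rest on marker RNA alone. Macrophage-like, NK-like, monocyte-like and CD8 T-like cells were the 4 with the most cells. Because cells were sorted on CD45, every share is a share of sorted cells and not of the tumour. Ptprc, the gene of CD45, read 596 CPM in vehicle, 569.5 CPM in MCB-294 and 596 CPM in MCB-36. The labels give male mice, and Xist, the RNA of the inactive X chromosome, read 0.0671, 0.0880 and 0.0439 CPM in vehicle, MCB-294 and MCB-36. The Y-linked genes Ddx3y (48.6, 42.7 and 43.8 CPM), Eif2s3y (33.2, 35.4 and 42.1 CPM), Kdm5d (8.74, 7.05 and 7.83 CPM) and Uty (11.0, 9.35 and 9.57 CPM) were read in all 3 libraries. Cd3e, a chain of the T cell receptor complex, read 70.6, 88.6 and 58.8 CPM, and Trac, the receptor's alpha constant region, 92.7, 101 and 79.9 CPM. A shared direction of both compounds against vehicle can come from the 1 vehicle library that both were set against.

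**Figure D1:**
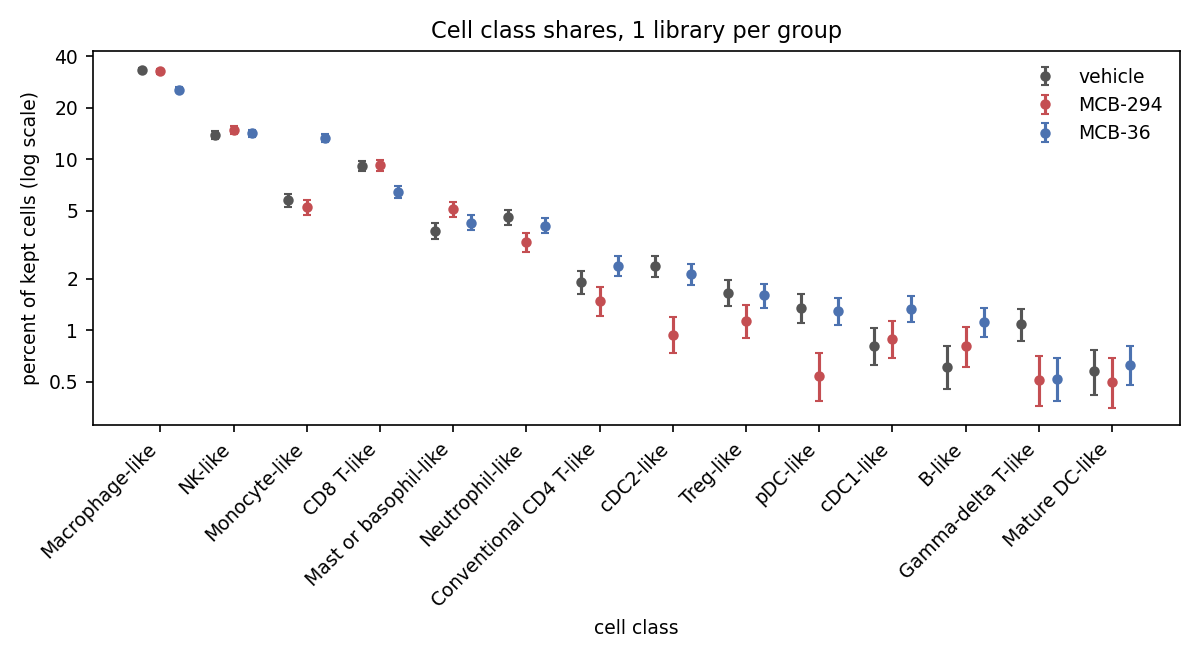
Share of each named cell class among the kept cells of each library, in percent on a log scale, with exact 95% binomial intervals (counting error only, 1 library per group). Monocyte-like cells stand at 13.3% in MCB-36 against 5.75% in vehicle and 5.24% in MCB-294, and cDC2-like and pDC-like cells are lowest in MCB-294.

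The first comparison, MCB-294 against vehicle, asks what the inhibitor did to the tumour's white blood cells. In macrophage-like cells, genes that report signalling through the MAPK pathway, the main route downstream of RAS proteins, were lower in the MCB-294 library, with a median log2 ratio of -1.03. Dusp6, a phosphatase switched on by ERK, read 32.4 CPM against 135 CPM. Proliferation genes were lower there too, at a median of -1.84, while genes of MHC class II antigen presentation were higher, at a median of 1.35. Conventional dendritic-like cells of type 2 (cDC2) made up 0.942% (0.732 to 1.19) of cells against 2.36% (2.04 to 2.72), and plasmacytoid dendritic-like cells 0.540% (0.384 to 0.738) against 1.34% (1.10 to 1.62).

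Among the other classes, gamma-delta T-like cells stood at 0.512% (0.361 to 0.706) in MCB-294 and 1.08% (0.868 to 1.33) in vehicle, a share ratio of 0.473 (0.323 to 0.694). The share ratio was 0.398 (0.302 to 0.524) for cDC2-like cells, a class that did not form at a mitochondrial limit of 20%, a minimum of 500 genes or resolution 0.5, and 0.402 (0.279 to 0.579) for pDC-like cells. Mast or basophil-like cells stood at 5.08% (4.59 to 5.62) against 3.80% (3.39 to 4.24), and neutrophil-like cells at 3.27% (2.87 to 3.71) against 4.57% (4.12 to 5.05). Treg-like cells stood at 1.14% against 1.66%, and conventional CD4 T-like cells at 1.48% against 1.90%, where the log2 ratio of -0.36 turned to 0.037 with a minimum of 500 genes per barcode. Macrophage-like (32.6% against 33.2%), NK-like (14.8% against 13.8%), monocyte-like (5.24% against 5.75%) and CD8 T-like shares (9.20% against 9.12%) had ratio intervals that held 1, as did those of cDC1-like, B-like and mature dendritic-like cells. With each library clustered separately the log2 share ratio was -0.78 for monocyte-like and -0.21 for CD8 T-like cells, and with each cell classed by its markers it was -0.46 for monocyte-like and 0.25 for macrophage-like cells. Clustering without the genes that differed between libraries gave -0.23 for macrophage-like cells.

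Kras RNA itself was higher in MCB-294, at 208 CPM (205 to 211) over all kept cells against 137 CPM (135 to 139) in vehicle. It was higher in macrophage-like cells (180 CPM against 135 CPM), NK-like cells (231 CPM against 146 CPM), monocyte-like cells (295 CPM against 169.6 CPM) and CD8 T-like cells (231 CPM against 131 CPM). Hras (82.5 CPM against 74.8 CPM) and Nras (83.7 CPM against 80.0 CPM) differed less over all kept cells. In macrophage-like cells the list of 5 RAS genes had a median of 0.42, above the range of 95% of 10000 random lists matched on expression (-0.35 to 0.21), called the random range below. The list's median was 0.25 in monocyte-like, 0.12 in NK-like and 0.05 in CD8 T-like cells.

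**Figure D2:**
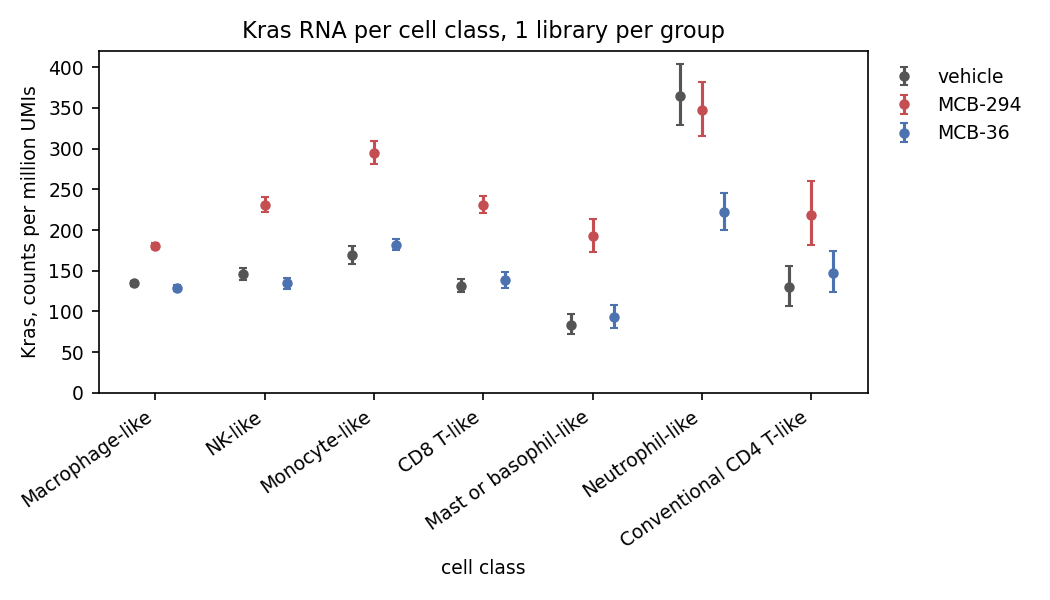
Kras RNA in counts per 1000000 UMIs (vertical axis, from 0) in 7 cell classes of the 3 libraries, with exact 95% Poisson intervals (counting error only, 1 library per group). The MCB-294 points are the highest in 6 classes, and in neutrophil-like cells MCB-36 is the lowest at 222 CPM.

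In macrophage-like cells 15 of the 17 MAPK output genes were measured, 14 of them were lower and 1 was higher, and the median lay below all random lists. Dusp4 (-2.15, -2.48 to -1.83), Dusp6 (-2.07, -2.15 to -1.98) and Etv4, a transcription factor induced by ERK (-1.60, -2.50 to -0.78), were the members with the largest ratios. The dissociation response, read with the list of heat shock and immediate early genes, had a median of 0.00 here, inside its random range (-0.20 to 0.12). Of the 13 proliferation genes 12 were lower, with Ccnb2 at 4.85 CPM against 48.4 CPM and Mki67 at 31.4 CPM against 182 CPM. The histone gene Hist1h2ap read 13.9 CPM against 209.6 CPM, Hist1h2ae 25.1 CPM against 148 CPM and Ube2c, which marks dividing cells, 15.1 CPM against 119.6 CPM. All 8 MHC class II genes were higher, led by H2-Eb1 (1.65, 1.64 to 1.67) and H2-Ab1 (1.56, 1.55 to 1.58). Genes of the interferon-gamma response had a median of 0.65 and 18 of 19 were higher, with the T cell attractant Cxcl9 at 2344 CPM against 586 CPM and the MHC class II activator Ciita at 52.3 CPM against 21.7 CPM. The type I interferon list lay on the other side, at -0.42, with Rsad2 at 109 CPM against 206 CPM. MHC class I genes had a median of 0.39, led by H2-T23 (472 CPM against 280.1 CPM).

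Lipid carrier and complement genes were also higher in macrophage-like cells of the MCB-294 library. Apoe read 15111 CPM against 4327 CPM, Apoc2 123 CPM against 35.9 CPM and complement C3 124 CPM against 43.5 CPM, and the complement, lipid and phagocytosis list had a median of 0.55 with 10 of 12 members higher. Klf9, a transcription factor gene, read 116 CPM against 25.2 CPM (2.21, 2.12 to 2.29). Monocyte-attracting chemokines were lower, with Ccl12 at 333 CPM against 2127 CPM, Ccl2 at 941 CPM against 3817 CPM and Ccl7 at 573 CPM against 1942 CPM, while Ccl8 was higher at 2420 CPM against 1061 CPM. That chemokine list had a median of -0.58. Inflammatory cytokines (median -0.79, 9 of 11 lower) included Il6 (-1.15, -1.71 to -0.61) and Cxcl3 (32.5 CPM against 69.1 CPM), which neutrophil-like cells hold at far higher levels, and Nos2, the inducible nitric oxide synthase, was higher (1.11, 0.97 to 1.24). The macrophage-like class leaves out the unnamed cluster 3, which lies nearest to macrophages. Cxcl1, Cxcl2, Cxcl3 and Ptgs2 of this list are among the leading genes of that cluster. The unfolded protein and integrated stress list had a median of -1.13 with all 9 measured members lower, among them Asns, an enzyme of asparagine synthesis, at 5.81 CPM against 22.9 CPM. Genes of alternative and suppressive macrophages had a median of 0.64 but went both ways: Spp1 (osteopontin) was lower at 433 CPM against 1306 CPM and Il10 lower at 2.99 CPM against 6.99 CPM, whereas Retnla read 1.26 CPM against 0.0922 CPM. The hypoxia and glycolysis list stood at -0.24 and the p53 and apoptosis list at 0.05, inside its random range.

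In monocyte-like cells of the MCB-294 library Saa3, an acute phase protein gene, read 3761 CPM against 55.3 CPM (6.09, 5.92 to 6.26), Wfdc21 579 CPM against 13.9 CPM, S100a8, a subunit of calprotectin, 10348 CPM against 1204 CPM, and Lrg1 439.6 CPM against 52.3 CPM. S100a8 read 96.4 CPM in the macrophage-like cells of the same library and 89160 CPM in its neutrophil-like cells. The neutrophil granule and maturation list had a median of 2.30 in monocyte-like cells, above its random range (-0.27 to 0.18), with 6 of 8 measured members higher and 2 lower. Ly6c2 was lower at 145 CPM against 779.9 CPM and Ly6c1 at 38.4 CPM against 226 CPM. The chemokines Ccl2 (234 CPM against 1615 CPM) and Cxcl3 (199 CPM against 1024 CPM) were lower as well, and the chemokine list had a median of -1.01. Cxcl3 is a leading gene of the unnamed cluster 3, which the monocyte-like class also leaves out. MAPK output genes had a median of -0.85 (10 of 13 lower), the type I interferon list -0.66, the inflammatory cytokine list -0.55, the stress list -0.73 and the alternative and suppressive list -0.49, each below its random range. The heat shock and dissociation list was also lower in these cells, at -0.22, below its random range (-0.19 to 0.12).

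NK-like cells showed the same MAPK output list at a median of -1.01, with 7 of 11 measured members lower, among them Spry4 (-1.75, -2.62 to -0.96) and Spred2 (-1.41, -1.79 to -1.04), which are feedback inhibitors of the pathway. Their proliferation genes had a median of -0.56 with all 13 lower, and Mki67 read 156 CPM against 244 CPM. Klf2, a quiescence factor of lymphocytes, was higher at 1389 CPM against 542 CPM, as were Rhob (175 CPM against 87.2 CPM), Fkbp5 (126 CPM against 70.8 CPM) and Adgre5 (344 CPM against 199 CPM). Gzmg (343 CPM against 589.8 CPM), Hist1h2ap (75.5 CPM against 289 CPM) and Hist1h2ae (132 CPM against 207 CPM) were lower. The cytotoxic effector list had a median of -0.0028, with 5 of 11 members higher and 3 lower. The type I interferon list stood at -0.34, the hypoxia and glycolysis list at -0.33 and the heat shock and dissociation list at -0.15, each below its random range.

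In CD8 T-like cells Xcl1, which attracts cross-presenting dendritic cells, was higher at 383 CPM against 122 CPM, with Jaml at 286 CPM against 135 CPM, Klf2 at 545 CPM against 258 CPM and Il18r1 at 216 CPM against 103 CPM. The granzymes Gzmd (57.6 CPM against 357 CPM), Gzme (42.8 CPM against 194 CPM) and Gzmf (262 CPM against 892 CPM) and the histone gene Hist1h2ap (107 CPM against 458 CPM) were lower. The MAPK output list stood at -0.19, inside its random range (-0.20 to 0.14), although Egr1 was lower (-1.30, -1.48 to -1.13). Exhaustion genes had a median of -0.15, with Tox, a factor of exhausted T cells, at 107 CPM against 195 CPM, and the naive and memory list stood at 0.17, as did the T cell activation list. The type I interferon list was at -0.36, the proliferation list at -0.17 and the hypoxia and glycolysis list at -0.29, below their random ranges, and the interferon-gamma (-0.09), MHC class I (-0.04), cytotoxic (-0.05) and stress (-0.15) lists lay inside theirs, with the heat shock and dissociation list at -0.01.

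Neutrophil-like cells of the MCB-294 library held RNA of secondary granules, which developing neutrophils make in the bone marrow. Camp, the cathelicidin gene, read 2253 CPM against 1.956 CPM (2 UMIs; 10.17, 8.32 to 13.22), Ltf (lactoferrin) 553 CPM against 6.84 CPM and Ngp 3278 CPM against 73.3 CPM. The granule and maturation list had a median of 1.77, with 10 of 12 members higher. MAPK output genes (median -1.46, all 6 measured lower), inflammatory cytokines (-1.32) and the type I interferon list (-0.79) were lower, with the heat shock and dissociation list at -0.54, inside its random range. In this class the scaling factors TMM and median of ratios would raise every log2 ratio by 0.25 and 0.24.

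**Figure D3:**
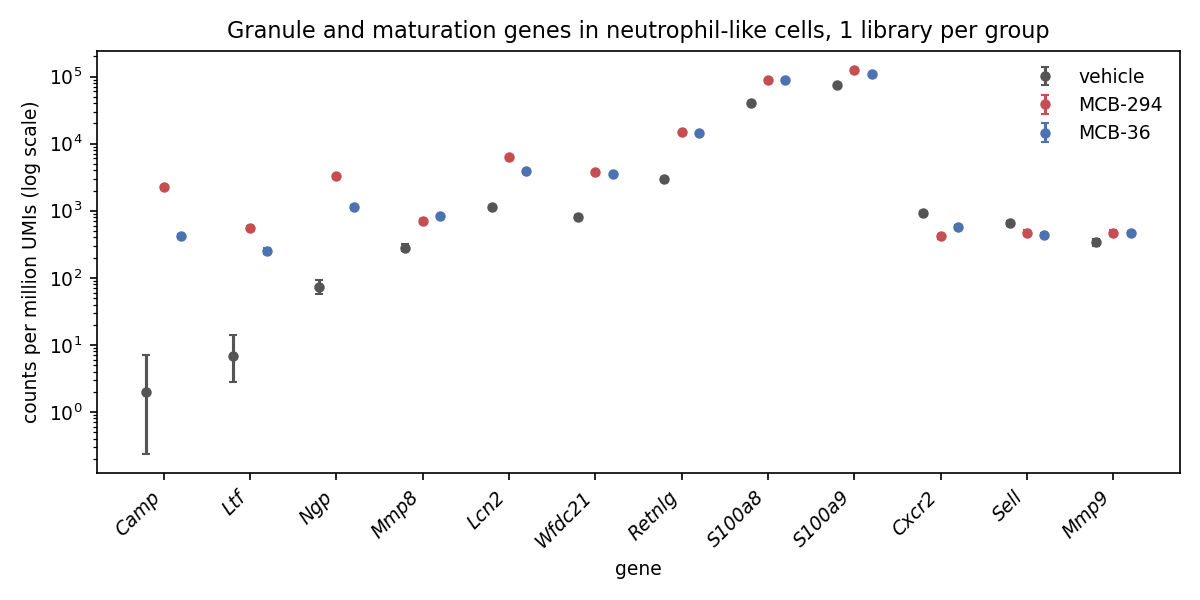
Granule and maturation genes in neutrophil-like cells of the 3 libraries, in counts per 1000000 UMIs on a log scale, with exact 95% Poisson intervals (counting error only, 1 library per group). Camp stands at 1.956 CPM in vehicle, 2253 CPM in MCB-294 and 415 CPM in MCB-36.

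The macrophage-like values mix clusters: cluster 0 held 77.0% of the class in MCB-294 and 9.67% in vehicle, cluster 2 held 4.80% and 48.8%, the cycling cluster 7 held 4.08% and 21.9% and cluster 13 held 3.57% and 9.30%. Genes named above are among the leading genes of these clusters (Cxcl9 and Apoe of cluster 0, Ccl12 and Ccl2 of cluster 2, Hist1h2ap and Ube2c of cluster 7, Rsad2 of cluster 13). Of CD8 T-like cells, cluster T1 held 44.9% in MCB-294 and 55.0% in vehicle, and cluster T3 34.0% and 19.8%. Cluster T9, with Gzmg among its leading genes, held 4.88% of NK-like cells in MCB-294 and 6.04% in vehicle, and cluster T6, led by Mki67 and histone genes, 8.07% and 12.4%. Macrophage markers in other classes, where they can come from free RNA, read 268 CPM in MCB-294 and 141 CPM in vehicle in NK-like, 274 CPM and 139 CPM in CD8 T-like and 1019.7 CPM and 586 CPM in neutrophil-like cells, and free RNA can equally add to Egr1, Il6, Il10, Cxcl3 and Retnla in macrophage-like cells and Egr1 in CD8 T-like cells, all below 0.1 of their level in another class.

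The second comparison, MCB-36 against vehicle, asks the same of the degrader. Monocyte-like cells made up 13.3% (12.6 to 14.0) of the MCB-36 library and 5.75% (5.25 to 6.28) of the vehicle library, a share ratio of 2.32 (2.09 to 2.57). Macrophage-like cells made up 25.5% (24.6 to 26.3) against 33.2% (32.2 to 34.2), and CD8 T-like cells 6.44% (5.95 to 6.95) against 9.12% (8.50 to 9.77). In macrophage-like cells MHC class II genes were higher at a median of 0.67 and proliferation genes lower at -0.63. Inflammatory cytokine genes were lower in monocyte-like cells, at a median of -1.10, with Il6 at 3.10 CPM against 24.8 CPM.

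The monocyte-like share depended on how cells were classed: its log2 ratio was 1.21 with clusters of all libraries together, 0.60 with each library clustered separately and 0.42 with each cell classed by its markers. All of these cells lay in cluster 4, whose leading genes include Saa3 and Lrg1. Of the 2101, 1968 kept the monocyte name when the 1014 genes over the cut for differing between libraries were left out of the clustering. The share ratio was 0.767 (0.732 to 0.803) for macrophage-like cells, 0.705 (0.636 to 0.782) for CD8 T-like cells and 0.478 (0.337 to 0.678) for gamma-delta T-like cells (0.518% against 1.08%). It was above 1 for cDC1-like cells, which present antigen to CD8 T cells (1.33%, 1.11 to 1.58, against 0.809%, 0.625 to 1.03), B-like cells (1.11%, 0.908 to 1.34, against 0.610%, 0.451 to 0.805) and conventional CD4 T-like cells (2.38% against 1.90%), although the log2 ratio of 0.86 for B-like cells turned to -0.97 with each library clustered separately. The B-like class also holds plasma-type cells: the plasma markers Jchain and Mzb1 are among its leading genes. Clustered without the genes that differed between libraries, 43 of its 212 cells took the plasma name. NK-like (14.1% against 13.8%), cDC2-like (2.12% against 2.36%), pDC-like (1.29% against 1.34%), Treg-like (1.60% against 1.66%), mast or basophil-like (4.26% against 3.80%), neutrophil-like (4.09% against 4.57%) and mature dendritic-like shares had ratio intervals that held 1. Kras read 142.5 CPM (140.3 to 144.7) over all kept cells against 137 CPM, and was lower than in vehicle in neutrophil-like cells (222 CPM against 365 CPM). Hras read 77.6 CPM and Nras 78.5 CPM over all kept cells, and in macrophage-like cells the RAS list stood at 0.08, inside its random range.

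In macrophage-like cells Cxcl9 was higher at 1482 CPM against 586 CPM, with Upp1, a uridine-degrading enzyme gene, at 104 CPM against 45.1 CPM, Serpina3g at 237 CPM against 112 CPM and Apoe at 7800.4 CPM against 4327 CPM. The interferon-gamma list had a median of 0.45 with all 19 measured members higher, among them Socs1 (0.83, 0.72 to 0.94). The type I interferon list stood at 0.19 with 14 of 17 higher, led by Isg15 at 307 CPM against 223.5 CPM. All 8 MHC class II genes were higher, with H2-Eb1 at 1650.0 CPM against 934 CPM, and MHC class I genes stood at 0.15. The complement, lipid and phagocytosis list stood at 0.29 and the alternative and suppressive list at 0.32, where 6 of 12 members were higher and 4 lower. Genes of other cell types were higher in these cells too, with the neutrophil granule and maturation list at 1.24 (S100a8 at 192 CPM against 49.7 CPM), the naive and memory T list at 0.52 and the cytotoxic effector list at 0.31, each above its random range. Cxcl1 (115 CPM against 263 CPM), a neutrophil attractant, Hspa1a (72.4 CPM against 157 CPM), an inducible heat shock protein, Hmox1 (292 CPM against 615 CPM), the haem oxygenase, and Hist1h2ap (99.4 CPM against 209.6 CPM) were lower. MAPK output genes had a median of -0.28 with 12 of 15 lower, led by Egr1 (-1.42, -1.49 to -1.35) and Dusp4 (-0.78, -1.02 to -0.54). The heat shock and dissociation list, which shares the immediate early kind of gene with them, was lower as well, at -0.27 with 13 of 15 lower. Inflammatory cytokines stood at -0.44, the chemokine list at -0.18, the stress list at -0.23 and the p53 and apoptosis list at -0.22, each below its random range, and the hypoxia and glycolysis list at -0.02, inside it.

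Monocyte-like cells of the MCB-36 library held Wfdc21 at 358 CPM against 13.9 CPM, Saa3 at 715 CPM against 55.3 CPM, Lrg1 at 226 CPM against 52.3 CPM and Apoc2 at 259 CPM against 80.8 CPM. The neutrophil granule and maturation list stood at 2.03 in them, above its random range (-0.24 to 0.17), with 7 of 9 measured members higher and 2 lower, and S100a8 read 5620 CPM against 1204 CPM. The neutrophil attractants Cxcl3 (199 CPM against 1024 CPM) and Cxcl1 (227 CPM against 700.4 CPM) were lower, with Pf4 at 57.8 CPM against 279 CPM and Hspa1a at 68.3 CPM against 184 CPM. Cxcl1, Cxcl3 and Pf4 are among the leading genes of the unnamed cluster 3, which the monocyte-like class leaves out. In the inflammatory cytokine list 10 of 11 members were lower, and Nos2 was higher (44.8 CPM against 23.8 CPM). The stress list stood at -0.70 with all 8 measured members lower, the alternative and suppressive list at -0.48 with Vegfa at 111 CPM against 283 CPM, and the MAPK output list at -0.47 with 9 of 13 lower. The heat shock and dissociation list stood at -0.44 beside them, with 13 of 15 lower. MHC class II (-0.28), type I interferon (-0.21) and chemokine genes (-0.31) lay below their random ranges, and proliferation (-0.12), hypoxia (-0.18), MHC class I (-0.13) and interferon-gamma genes (0.06) inside theirs. The chemokine median turned to 0.045 with a lower UMI minimum, and the MHC class II median to 0.21 with doublets kept.

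In NK-like cells Gadd45g, a stress-inducible gene, was higher at 459 CPM against 123.5 CPM, with the metallothionein Mt1 at 134 CPM against 54.7 CPM, Snhg15 at 102 CPM against 45.5 CPM and Gzme at 496 CPM against 278 CPM. Rgs2 (186 CPM against 314 CPM), Ubc (145 CPM against 234 CPM), Cd7 (76.8 CPM against 123 CPM) and Ccnl1 (141 CPM against 220.3 CPM) were lower. The type I interferon list stood at -0.62 with all 14 measured members lower, the MAPK output list at -0.43 with 9 of 12 lower and, beside them, the heat shock and dissociation list at -0.50 with all 15 lower. The cytotoxic effector (-0.01) and proliferation lists (-0.12) lay inside the random range, as did the interferon-gamma (-0.17), MHC class I (-0.11), hypoxia (0.06) and stress lists (-0.21).

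In CD8 T-like cells Ifng, the gene of interferon gamma, was higher at 738 CPM against 373 CPM, with Xcl1 at 334 CPM against 122 CPM, Ccl1 at 167 CPM against 83.4 CPM and Jaml at 268 CPM against 135 CPM. Tox read 65.1 CPM against 195 CPM (-1.58, -1.76 to -1.41), Nr4a2 152 CPM against 334 CPM, Nrn1 48.5 CPM against 115 CPM and Gzmc 159.6 CPM against 342 CPM. The exhaustion list, which holds Tox and Nr4a2, had a median of -0.18 with 5 of 10 lower and 2 higher. The naive and memory list stood at 0.35, led by Tcf7 (22.8 CPM against 14.8 CPM), and the type I interferon and interferon-gamma lists at 0.30 and 0.27, all above their random ranges. Proliferation genes stood at -0.30 and stress genes at -0.33, below their ranges, with the heat shock and dissociation list at -0.16, and the MAPK output (-0.20), cytotoxic (-0.10), T cell activation (0.02), MHC class I (0.01) and hypoxia lists (0.06) lay inside theirs.

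Neutrophil-like cells held Camp at 415 CPM against 1.956 CPM (7.73, 5.87 to 10.78), Ltf at 252 CPM against 6.84 CPM and Ngp at 1149.6 CPM against 73.3 CPM, and the granule and maturation list stood at 1.68. Their inflammatory cytokines (-0.83) and MAPK output genes (-0.76) lay below the random range together with the heat shock and dissociation list (-0.70). The scaling factors TMM and median of ratios would raise every ratio of this class by 0.15 and 0.13.

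**Figure D4:**
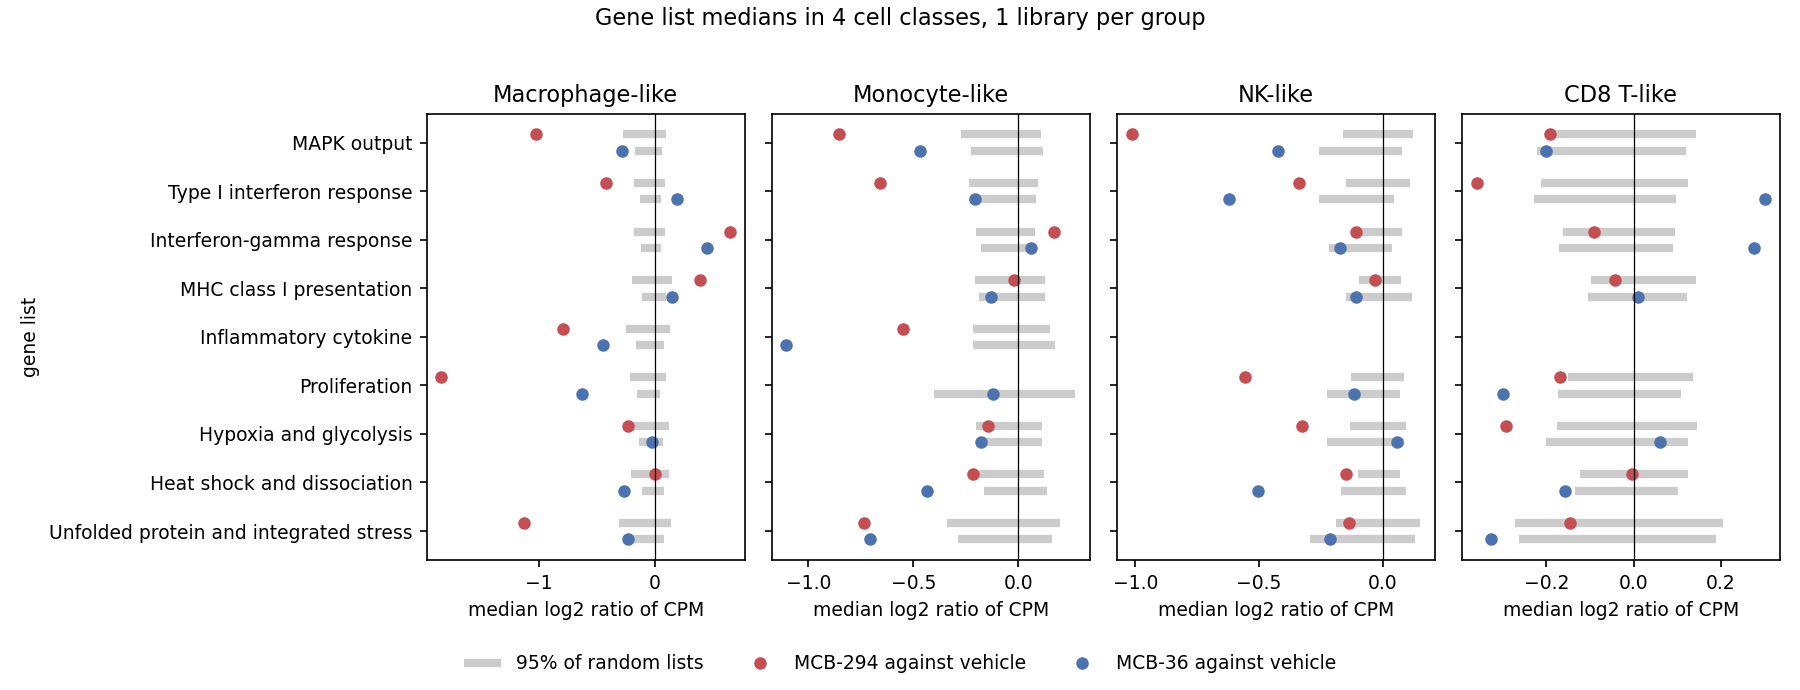
Median log2 ratio of CPM (horizontal axis) of the fixed gene lists (vertical axis) in 4 cell classes for MCB-294 and MCB-36 against vehicle, over the range of 95% of random lists matched on expression (grey), with 1 library per group, a scale of its own in each panel and blanks for lists with too few measured members or not described in that class. The MAPK output list stands at -1.03 for MCB-294 and -0.28 for MCB-36 in macrophage-like cells.

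Cluster 0 held 29.7% of the macrophage-like cells in MCB-36, cluster 2 held 35.6%, the cycling cluster 7 held 14.0% and cluster 13 held 8.14%. Of CD8 T-like cells, cluster T1 held 42.5% in MCB-36 and 55.0% in vehicle, and cluster T3 36.3% and 19.8%. Cluster T9, with Gadd45g and Gzme among its leading genes, held 9.87% of the NK-like cells in MCB-36, and cluster T6 12.3%.

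The third comparison sets MCB-36 beside MCB-294, the compound from which the title says the degrader was derived. The doses differed, 60 mg/kg against 30 mg/kg, so the values stand side by side. MAPK output genes in macrophage-like cells were higher in the MCB-36 library, at a median of 0.74 with 11 of 14 higher and 2 lower, and Dusp6 read 119 CPM against 32.4 CPM. Kras read 142.5 CPM against 208 CPM over all kept cells. Monocyte-like cells made up 13.3% against 5.24%, a share ratio of 2.55 (2.28 to 2.84).

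Against MCB-294, the MCB-36 library had share ratios of 0.780 (0.744 to 0.819) for macrophage-like, 0.700 (0.630 to 0.778) for CD8 T-like, 2.26 (1.72 to 2.96) for cDC2-like and 2.39 (1.67 to 3.42) for pDC-like cells. The macrophage-like log2 share ratio of -0.36 became -0.11 when clustered without the genes that differed between libraries and -0.51 with each library clustered separately. The ratio was 0.958 (0.889 to 1.03) for NK-like and 1.01 (0.660 to 1.55) for gamma-delta T-like cells, so a difference between the compounds was not detectable at this depth for these. In macrophage-like cells Kras had a ratio of -0.49 (-0.54 to -0.44), in NK-like cells -0.78 (-0.87 to -0.69), in monocyte-like cells -0.70 (-0.79 to -0.61) and in CD8 T-like cells -0.74 (-0.87 to -0.61).

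In macrophage-like cells Ccl12 (1555.5 CPM against 333 CPM) and Hist1h2ae (101 CPM against 25.1 CPM) were higher in MCB-36, and Cbr2 (43.7 CPM against 159 CPM) and Klf9 (37.9 CPM against 116 CPM) were lower. The proliferation list stood at 1.28, the chemokine list at 0.55, the stress list at 0.53 and the type I interferon list at 0.46, all above their random ranges. MHC class II genes stood at -0.72, the complement, lipid and phagocytosis list at -0.37, the heat shock and dissociation list at -0.31 and the interferon-gamma list at -0.29, all below. The inflammatory cytokine list, at -0.06, lay inside its range.

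Monocyte-like cells held more Ccl2 (846 CPM against 234 CPM) and Ly6c2 (322 CPM against 145 CPM) and less Saa3 (715 CPM against 3761 CPM) and Ifitm1 (450.0 CPM against 1498 CPM) in MCB-36. Their type I interferon list stood at 0.43, the MAPK output list at 0.22, the heat shock and dissociation list at -0.22 and the neutrophil granule and maturation list at -0.63. In NK-like cells, where cluster T9 held 9.87% against 4.88% and cluster T6 12.3% against 8.07%, Gadd45g (459 CPM against 93.8 CPM) and Snhg15 (102 CPM against 33.9 CPM) were higher, Klf2 (413 CPM against 1389 CPM) and Rhob (69.5 CPM against 175 CPM) were lower, and the MAPK output and proliferation lists stood at 0.46 and 0.39 with the heat shock and dissociation list at -0.46. In CD8 T-like cells Gzmd (174 CPM against 57.6 CPM) and Hist1h2ap (226 CPM against 107 CPM) were higher and Adgre5 (137 CPM against 262 CPM) and Klf2 (286 CPM against 545 CPM) lower. The type I interferon list stood at 0.70 there, with 13 of 14 members higher, and the MAPK output list at 0.06, inside its range. Neutrophil-like cells held less Camp (415 CPM against 2253 CPM) and Ngp (1149.6 CPM against 3278 CPM).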

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

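The comparison of pair types within a library was chosen after the counts of mixed barcodes had been seen, as was the demand that the whole interval, not the value alone, lie within 1.5-fold before random co-loading was taken as enough, and as was the reading of dissociation for each library by itself.

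Of the 7 clusters that no comparison uses, because their markers fit no single class, some held more and some fewer cells in the treated libraries than the vehicle control. Cluster 5, with macrophage and T cell markers, held 7.65% of kept cells in MCB-294 and 5.50% in MCB-36 against 3.41% in vehicle. Cluster 16, with macrophage and NK markers, held 2.84% in MCB-294 and 2.15% in MCB-36 against 0.286% in vehicle. Cluster T11, with granzyme genes leading, held 0.962% in MCB-36 and 0.609% in MCB-294 against 0.573% in vehicle. Cluster 3, nearest to macrophages, held 7.85% in MCB-294 and 8.40% in MCB-36 against 10.2% in vehicle, and cluster 20 held 1.22% and 1.19% against 2.10%. The leading genes of cluster 20 include Col1a2 of the fibroblast markers and Tm4sf1 of the CT26 or epithelial markers, and its Ptprc read 50.9 CPM. Whether its cells are fibroblasts or CT26 tumour cells is not settled. Cluster 14 held 1.58% and 2.46% against 1.92%, and cluster 24 held 1.29% and 0.666% against 0.871%.

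Barcodes with both macrophage and T or NK markers may be droplets with 2 cells, cells still attached to each other, or macrophages that took up lymphocyte material. Before doublets were removed, 6.54% of MCB-294, 5.19% of MCB-36 and 3.44% of vehicle barcodes held macrophage and NK markers, and 44.9%, 51.4% and 75.1% of these were removed as doublets. C1q RNA in cluster 16 was at least 45.02 times that of NK-like cells. Because C1q genes helped place this cluster nearest to macrophages, that value was largely set beforehand and cannot decide on free macrophage RNA. The random number is the product of the numbers of barcodes with each marker set, over all barcodes, as if the 2 sets fell on barcodes independently. It is not the number that co-loading would give, which is lower because few droplets hold 2 cells. A value below 1 therefore does not mean fewer pairs than co-loading would bring. Relative to the random number, macrophage pairs with T or NK cells exceeded macrophage pairs with mast cells at least 5.12 times (2.89 to 9.06) within each library. This argues against co-loading at 1 rate for all cell types. Mast cell pairs with T cells stood at 0.911 (0.719 to 1.14) of the random number in MCB-36, 0.349 (0.232 to 0.504) in MCB-294 and 0.456 (0.298 to 0.669) in vehicle. Macrophage pairs with T cells stood at 1.05 (0.978 to 1.13), 0.900 (0.831 to 0.973) and 0.701 (0.634 to 0.772). The intervals of these 2 pair types lay apart in MCB-294 alone. Their overlap in MCB-36 and vehicle does not show that the 2 were alike there. Mast cell pairs with NK cells stood at 0.116, 0.0939 and 0.0537, below macrophage pairs with NK cells at 0.812, 0.683 and 0.517. Incomplete dissociation of all cell types was read from mast cell pairs against the random number, over that in vehicle. For MCB-294 this gave 0.907 (0.607 to 1.35), with its upper bound below the 1.5-fold set beforehand. But the interval reaches the gain of macrophage pairs with T or NK cells there, 1.29 (1.18 to 1.42), so it cannot decide. For MCB-36 it gave 1.86 (1.30 to 2.67), where dissociation stays open. The marker cuts were unequal, however. T cell markers needed 3 UMIs in MCB-36 and 4.75 in vehicle, and mast cell markers 9.75 and 16.25. Mast cell pairs with T cells numbered 77 in MCB-36 and 26 in vehicle, and those with NK cells 9 and 3. The MCB-36 value thus rests mainly on T cell pairs, to which the lower cuts can add. Random co-loading cannot be told apart for the difference from vehicle, since the gain of macrophage pairs with T or NK cells relative to that of mast cell pairs was 1.43 (0.944 to 2.15) in MCB-294 and 0.824 (0.569 to 1.19) in MCB-36, and the treatment stays open as an untested biological difference.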

How the results depend on the processing

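Leaving out the cycling macrophage cluster, leaving clusters 5 and 16 out of the total and clustering without the genes that differ were chosen after seeing the data, and the other alternatives were planned. Over all alternatives, shares of the 4 classes with the most cells stayed within their intervals in 116 of 132 values and the MAPK output list in them stayed near its value, on the same side of its random range, in 82 of 87. A share or list median counts as reversed only if its own interval excludes 0 or it lies outside its random range, and it then changes sign, which none of these did, although the macrophage-like and CD8 T-like shares of MCB-294 against vehicle, whose intervals hold 0, took both signs. The same held for other shares in 307 of 314 (2 reversed), other described lists in 1231 of 1388 (7 reversed) and named genes in 341 of 480 (0 reversed). For lists, TMM and median of ratios shift a list and its random lists alike, so no list could change side of its range. Under each of them 12 of 12 MAPK output values and 191 of 191 values of other described lists counted as unchanged. Because the described pairs of list and class were chosen after a first look, every pair was counted too, and 25 of 2677 list values reversed. These were 7 of 1475 among the pairs described and 18 of 1202 among those not described, so the described pairs reversed less often. Without the guard against free RNA, 26, 23 and 12 of the genes named for the 3 comparisons, in the order of the report, were named again. No cDC2-like class formed with a minimum of 500 genes, a mitochondrial limit of 20% or resolution 0.5, and with separate clustering some libraries had no cDC2-like, gamma-delta T-like or conventional CD4 T-like cluster, so these have no value there. Depth limits the smaller classes: in the simulation 67 of 67 genes with a 1.5-fold difference had the right direction in macrophage-like counts and 64 of 67 in neutrophil-like counts. The interval excluded a log2 ratio of 0 on the right side for 59 and 46 of them. The cause was not tested for any of the values below.

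With each library clustered separately, the log2 share ratio was -0.48 for macrophage-like cells (MCB-36 against vehicle) and -0.51 (MCB-36 against MCB-294), -0.78 and 0.60 for monocyte-like cells (MCB-294 and MCB-36 against vehicle), -0.21 and -0.82 for CD8 T-like cells (MCB-294 and MCB-36 against vehicle) and -0.97 for B-like cells (MCB-36 against vehicle, reversed). With a class per cell from markers it was 0.25 and -0.15 for macrophage-like and -0.46 and 0.42 for monocyte-like cells (MCB-294 and MCB-36 against vehicle), and 0.89 for monocyte-like cells between the compounds. Clustering without genes that differ gave -0.23 (MCB-294 against vehicle) and -0.11 (MCB-36 against MCB-294) for macrophage-like cells, whose MCB-294 value against vehicle was 0.041 as a share of named immune classes and 0.080 without mixed clusters. Resolution 2 gave -0.21 for CD8 T-like cells and a minimum of 500 genes 0.037 for conventional CD4 T-like cells (reversed), both MCB-294 against vehicle.

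Among list medians, a minimum of 10 UMIs gave 0.045 for chemokines in monocyte-like cells (MCB-36 against vehicle, reversed), 0.14 and 0.13 for MAPK output in monocyte-like and CD8 T-like cells (MCB-36 against MCB-294) and 0.21 for T cell activation in conventional CD4 T-like cells (MCB-36 against MCB-294, reversed). Keeping doublets reversed MHC class II (0.21) and chemokines (0.024) in monocyte-like cells (MCB-36 against vehicle) and heat shock and dissociation (0.0096) in conventional CD4 T-like cells (MCB-294 against vehicle). Thinned UMIs gave 0.26 for chemokines in monocyte-like cells (MCB-36 against vehicle, reversed), and a mitochondrial limit of 20% gave 0.11 for MAPK output there (MCB-36 against MCB-294). The mean over cells gave -0.25 (MCB-294 against vehicle) and 0.12 (MCB-36 against MCB-294) for MAPK output in CD8 T-like cells, and reversed exhaustion there to 0.012 (MCB-36 against MCB-294).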

Other observations

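The genes in the next 2 paragraphs were chosen after their values were seen, as was the test of free RNA for Klf9 and Fkbp5. In mast or basophil-like cells, Gzmf read 151 CPM in MCB-294 against 7.01 CPM in vehicle, Klf3 114 CPM against 16.4 CPM and Iigp1, an interferon-induced GTPase gene, 121 CPM against 45.8 CPM. Their proliferation list had a median of -1.55 in MCB-294 against vehicle, with all 11 measured members lower, and the histone gene Hist1h2ap read 8.07 CPM against 168 CPM. Cluster 28, the smaller of the 2 clusters of this class, held 2.18% of it in MCB-294 and 10.8% in vehicle. Mcpt8, a protease gene of basophils, read 232 CPM in MCB-36 and 68.9 CPM in MCB-294. The MAPK output list stood at -0.10 for MCB-294 and 0.05 for MCB-36 against vehicle and the heat shock and dissociation list at -0.08 and -0.10, all inside their random ranges, although Dusp6 read 40.9 CPM in MCB-294 against 85.1 CPM. Neutrophil-like cells held the cystatin-family gene Stfa3 at 886 CPM in MCB-294 and 903 CPM in MCB-36 against 7.82 CPM in vehicle, and less Thbs1 (24.4 and 112 CPM against 463 CPM), Egr1 (105 and 474 CPM against 1963 CPM) and Acta2 (3.26 and 20.1 CPM against 114 CPM).

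In conventional CD4 T-like cells, Ccl1 read 961 CPM in MCB-294 and 467 CPM in MCB-36 against 75.4 CPM in vehicle, Ccl5 942 and 599 CPM against 261 CPM, and Ccl4 72.1 and 819.7 CPM against 204 CPM. Gata3, the factor of type 2 helper cells, read 149 and 119.8 CPM against 268 CPM, and Gadd45b 107 and 132 CPM against 263 CPM. The Treg activation list stood at -0.08 and -0.14, inside its random ranges, with Ctla4 at 441 and 557 CPM against 376 CPM. MAPK output genes stood at -0.48 and -0.32, below their ranges, with the heat shock and dissociation list at -0.15 and -0.28. Macrophage markers in these cells, where they can come from free RNA, read 439 and 278 CPM against 186 CPM. The naive and memory list (0.07 and 0.15) and the T cell activation list (0.03 and -0.25) lay inside theirs.

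The lower MAPK output list in macrophage-like cells of the MCB-294 library (-1.03) may reflect less MAPK signalling in these cells, or a technical difference between the 2 libraries. A shift of cells between clusters is argued against by the 3 macrophage clusters with at least 100 cells in both libraries, where the median lay between -0.99 and -0.64. With UMIs thinned the median was -1.04, but thinning a library evenly barely alters a ratio of CPM, so this cannot decide on depth. Macrophage-like cells had median depths of 18552 UMIs in MCB-294 and 19032 in vehicle. Without Egr1, Ier3 and Fosl1 the median was -1.05 (random range -0.28 to 0.11), so it does not rest on these genes. With 14 of 15 members lower it could hardly have risen into that range, so this cannot decide on a dissociation response. The heat shock and dissociation list stood at -0.0026 in these cells, inside its random range (-0.20 to 0.12). A hypothesis that stays open is an action of the compound on these cells, directly or through the tumour, and with 1 library it cannot be separated from a difference between mice.

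Klf9 and Fkbp5, both induced by corticosteroid hormones, were higher in MCB-294 than in vehicle in all 7 compared classes, for example Fkbp5 at 195 CPM against 79.8 CPM in macrophage-like cells. A list of 12 other corticosteroid-responsive genes, written before it was measured, lay above its random range in 5 of the 7 classes, with medians of 0.65 in macrophage-like and 0.69 in mast or basophil-like cells. It did not in monocyte-like (-0.02) and neutrophil-like cells (-0.34), and for MCB-36 against vehicle it lay above its range in macrophage-like (0.16), CD8 T-like (0.13) and mast or basophil-like cells (0.35) and below it in monocyte-like (-0.34) and neutrophil-like cells (-0.62), with Fkbp5 higher in 5 classes but Klf9 higher only in macrophage-like and mast or basophil-like cells and lower in NK-like (-0.33) and monocyte-like cells (-0.55). Free RNA as the source is argued against in NK-like, CD8 T-like, neutrophil-like and conventional CD4 T-like cells. Their gain of both genes was at least 2.41 times, and up to 11.8 times, what free RNA at the level of mast or basophil-like cells, the highest class, would bring. For mast or basophil-like cells themselves this bound cannot decide. A higher corticosteroid level may be behind the MCB-294 pattern, from handling or illness as well as from the compound, whether it reaches the MCB-36 library stays open, and no hormone value is in the labels.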
